A study of Oryctolagus cuniculus with 20 samples.

How the data were processed

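Condylar cartilage of the rabbit temporomandibular (jaw) joint was profiled on 20 one-colour microarrays, 1 RNA sample per array. The arrays fall into 5 groups of 4, per the labels: untreated rabbits and rabbits sampled 1, 2, 4 or 8 weeks after surgery that deranged the left joint. The design text puts the 4 untreated and 16 operated rabbits in separate groups, so arrays were treated as separate animals. No group is labelled as sham-operated, and the same untreated group, labelled with no time, serves as control at every time. Effects of the operation itself or of time passed therefore cannot be told apart from those of derangement, also within a scan day.

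The values used were the deposited intensity of each spot, in arbitrary linear units. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1 under protocol GE1_107_Sep09, which subtracts background, corrects spatial trends within the array and replaces low signals by a small positive value. The authors' value table, also intensity, was compared with the scanner values over the 43603 probes found in both. Its columns lay within 0.001 log2 units of the scanner values of their own array for 16 arrays, and its scale is therefore linear with no centring. Each of the 4 columns of the 8-week group equalled another array of that same group instead, so replicate numbers within that group are uncertain in 1 of the sources. Column medians of that table ran from 28.26 to 90.0.

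Every array held 43803 spots other than controls. Spots marked as outliers by the scanner software, 5 to 62 per array, were left out, and 50 probes printed as 5 spots each were averaged. No spot was saturated. Between 7957 and 14027 spots per array carried the small positive value that replaces a low signal, the most on 1-week replicate 4. Levels of dim probes rest in part on these values. The share of spots well above background ran from 49.1% to 66.4% per array. The 75th percentile of signal ran from 174.1 to 641.8. The number of arrays, 4 per group, limits the precision of each mean.

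Intensities were put on the log2 scale and each array's 75th percentile was subtracted, so levels are log2 units relative to that percentile. A probe was kept if it was well above background on at least 3 of the 4 arrays of at least 1 group, which held for 26905 of 43603 probes (61.7%). Differences were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in a model of the 5 group means over all 20 arrays. All groups thus share a common spread estimate for each probe. The median SD of the kept probes was 0.329 in the 1-week group and 0.2 to 0.237 in the other groups. The common estimate can therefore understate the error of comparisons with 1 week. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the kept probes of a comparison, with a call at adjusted p under 0.05. Errors of differences are standard errors (SE) of that fit, and errors of group levels are standard deviations (SD) over 4 arrays. The 8 planned comparisons were each operated group against control, 2 weeks against 1 week, 4 against 2, 8 against 4 and 8 against 1. An F test asked for any difference among the 5 groups. A comparison of 4 weeks with 1 week was added after the data had been seen, because both groups were scanned on the same day.

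Where a probe was not well above background on any array of 1 of the groups compared, the change is given as a bound. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own level and the lowest level of any probe well above background on that array. No fold is given where that ratio was under 1 or where neither group was above background. Where a probe was well above background on only some arrays of a group, the change is the fitted value and rests in part on dim arrays.

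Gene names came from the files and from a RefSeq table of rabbit genes. A name was found for 3190 probes (7.32%): 1866 by RefSeq accession, 729 by the description in the files, 263 by a gene name of the files found in the table, 179 by an Ensembl transcript shared with a named probe, 137 by a LOC number, and 16 by the file's name kept as given. The other 40413 probes, many of the 29619 identified by Ensembl transcript among them, are unnamed here and enter the counts of probes alone. Of 1046 distinct named genes, 765 had a kept probe, and each gene's value is its kept probe of the highest mean. Where other probes of a named gene went the other way, this is stated.

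The genes named in the text follow a rule fixed, with the tests, the gene lists and most alternatives, before the data were examined. For each comparison with control it takes the 8 largest rises and 8 largest falls among called genes whose 4 operated arrays all lay above, or all below, the 4 control arrays. For comparisons between times it takes 4 of each, for each gene list up to 4 members with the lowest F test p, and in addition a fixed panel of cartilage and joint disease genes. In 4 arrays against 4, chance gives such complete separation for 2.86% of genes. List members that were called but stand outside that rule (CCL2, IL15, IL1RN, TLR4 and some muscle genes), the single probes called between 8 weeks and 1 week, and the immunoglobulin probes were named after their values were seen. Some called genes are counted but not reported here by name.

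The lists covered hyaline cartilage matrix, chondrocyte hypertrophy, fibrous matrix, matrix proteases, protease inhibitors, inflammatory mediators, interferon response, osteoblasts, osteoclasts, macrophages, lymphocytes, neutrophils, erythroid cells, endothelium, skeletal muscle, adipocytes, synovial lining, nerve, smooth muscle, cell cycle, TGF-beta and BMP signalling, WNT and hedgehog signalling, hypoxia and glycolysis, oxidative phosphorylation, the unfolded protein response, immediate early genes, and apoptosis. The 11 lists with at least 5 measured members were tested with camera in limma, which asks whether a list's genes shift against the other named genes. Its preset correlation between genes was 0.01, and p-values were adjusted over 11 lists and 4 comparisons at a time. The same test with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run as alternatives. Because the preset correlation is low, list calls are given with the value from an estimated correlation.

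Both steps were tested on simulated data built from these arrays, with 100 of 26905 probes changed 2-fold and 100 changed 4-fold. The share of 2-fold changes recovered ran from 52% in the F test to 64% for 2 weeks against 1 week, and that of 4-fold changes from 82% for 4 weeks against control to 91% for 2 or 8 weeks against control and for 8 weeks against 4. False calls made up 1.4% of all calls for 1 week against control, the lowest share, and 6.83% for 8 weeks against 4, the highest. Probes were drawn independently, without slide or scan day effects, so these shares need not hold for the real arrays. With no change simulated, some list was called in 2 of 100 draws over 765 genes. Genes were drawn independently there, so this share does not hold for lists of correlated genes. Splits of the real arrays called 6 or more lists against control in 39 of 100 cases, the real one included.

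Array position and scan day were read from the file headers. Each of 5 slides held 1 group, so slide and group cannot be told apart. Control and 2-week arrays were scanned on 1 day and the 1-, 4- and 8-week arrays on another. Values within a scan day are therefore possible for 2 weeks against control, 8 weeks against 4, 8 against 1 and 4 against 1, and for no other comparison. Scan day as a block is no separate test of these 4, because no group spans both days: it returned the same 122, 150, 4 and 289 probes as the fit without it. Alternatives covered background correction by normexp with an offset of 50, quantile normalization, median centring, the authors' value table, other filters on dim probes, outlier spots kept, other variance settings, array weights, a block for replicate number or slide position, scan day, a GC correction, a stricter threshold of 2-fold, and fits without each array in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.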

Results

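The study asked how the transcriptome of the condylar cartilage, the tissue that covers the jaw's articular head, changes in the weeks after surgical derangement of the joint. Each of the 5 groups, untreated control and 1, 2, 4 and 8 weeks after surgery, held 4 arrays. The lowest 75th percentile of signal, 174.1, and the lowest share of spots well above background, 49.1%, belonged to replicate 4 of the 1-week group. The highest of these values were 641.8 in replicate 3 of the 4-week group and 66.4% in replicate 3 of the 1-week group. Correlations between arrays of the same group had a median of 0.973 (0.933 to 0.985, 30 pairs) and those between groups 0.963 (0.899 to 0.98, 160 pairs), across probes, which are not independent replicates. The F test called 4260 of 26905 probes as differing among the 5 groups.

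The first principal component held 25.7% of the variance and the second 12.3%. All 4 control arrays (27 to 81.6) and all 4 of the 2-week arrays (19.4 to 44.3), which shared a scan day, had positive scores on the first. The 1-week arrays lay between -104.9 and -7.7, the 4-week arrays between -55.3 and -11.1 and the 8-week arrays between -33.3 and -3.2, and these 12 were scanned on the other day.

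**Figure D1:**
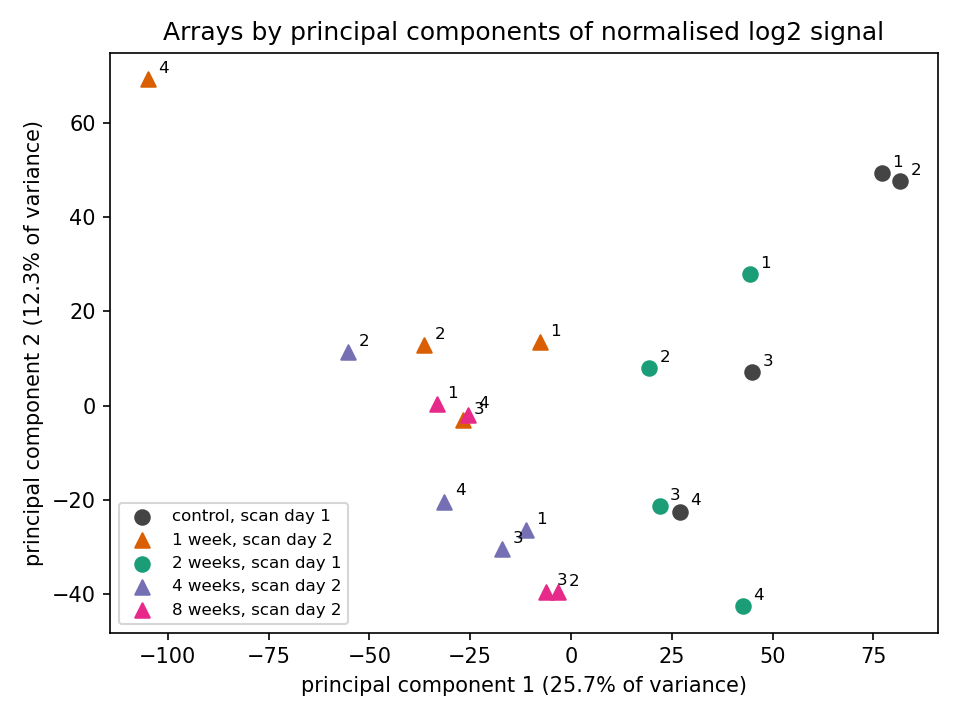
Scores of the 20 arrays on the first (x axis, 25.7% of the variance) and second (y axis, 12.3%) principal components of log2 level, 1 point per array and 1 colour per group. Control and 2-week arrays have first-component scores of 19.4 or more, and the arrays of the other 3 groups scores of -3.2 or less.

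Skeletal muscle transcripts were the largest named difference from control 1 week after surgery. The gene for TNNC2, the calcium-binding troponin subunit of fast muscle fibres, fell by 5.37 on the log2 scale (SE 1.06, adjusted p = 0.0022), from 4.06 ± 3.15 in control to -1.31 ± 0.75 (SD, n = 4 each). The log2 changes of the myosin heavy chain genes MYH8 and MYH1 were -5.98 ± 1.33 and -4.7 ± 1.05 (SE, adjusted p = 0.00582 and 0.0062). Those of ATP2A1, the calcium pump of fast fibres, and TTN, the giant sarcomere protein titin, were -4.55 ± 1.01 and -4.43 ± 0.98 (adjusted p = 0.00579 and 0.00572), and MYL11, a fast myosin light chain, changed by -3.66 ± 0.87 (adjusted p = 0.00959). CASQ2, a calcium store protein of muscle, and NEB, nebulin, were not well above background at 1 week and were at least 9.4-fold and 6.54-fold lower (adjusted p = 0.00794 and 0.0038). At 1 week MYH1 was well above background on 3 of 4 arrays, ATP2A1 and TTN on 2 and MYH8 on 1, so their changes are fitted values, not measured sizes. Without control replicates 1 and 2, the calls of MYH8, MYH1, ATP2A1 and TTN were lost, and the bound of NEB was 1.85-fold.

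Among the genes higher at 1 week, several were not well above background in control. PPARA, a nuclear receptor that drives fatty acid oxidation, was at least 4.05-fold higher (adjusted p = 7.87e-05) and TH, the rate-limiting enzyme of catecholamine synthesis, at least 1.9-fold (adjusted p = 8.26e-07). The gap junction gene GJA10 was at least 2.45-fold higher (adjusted p = 4.98e-09), CASP14, a caspase of keratinizing epithelium, at least 2.03-fold (adjusted p = 2.41e-05), and the motilin receptor gene MLNR at least 4.48-fold (adjusted p = 0.00472). The apolipoprotein gene APOC4 was at least 5.51-fold higher (adjusted p = 3.8e-05) and the uroplakin gene UPK1B at least 2.76-fold (adjusted p = 0.000319). OVGP1, an oviduct glycoprotein, rose by 2.69 ± 0.25 (SE, adjusted p = 1.22e-06) and was well above background on 1 of 4 control arrays. Each of the genes in this and the preceding paragraph lay beyond all 4 control arrays in all 4 of the 1-week arrays, and each kept its call without any 1 array.

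In the hyaline cartilage list (4 members measured), SOX9, the transcription factor of chondrocyte identity, was at least 1.99-fold higher at 1 week (adjusted p = 0.0194). It alone was called of COL2A1, ACAN, CNMD and SOX9, and 3 members were called higher when adjusted over the list alone. Without replicate 4 of the 1-week group or replicates 1 or 3 of control, SOX9 lost its call (adjusted p up to 0.0661). Of 10 WNT and hedgehog genes, 3 rose and 1 fell, the same numbers as when adjusted over the list alone. WNT11 changed by 2.19 ± 0.48 (adjusted p = 0.00561), IHH, the growth plate hedgehog ligand, by 1.96 ± 0.54 (0.0232), FRZB, a secreted WNT antagonist of cartilage, by 1.3 ± 0.34 (0.0171) and WNT3 by -1.63 ± 0.41 (0.0133). The calls of IHH (without 1-week replicate 4 or control replicates 1 or 2, adjusted p up to 0.0786) and FRZB (without 1-week replicate 4 or control replicate 3, up to 0.0617) were lost. IHH was also the 1 called gene of 6 in the hypertrophy list, where 4 members were higher and 1 lower when adjusted over the list alone.

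Inflammatory genes went both ways at 1 week: of 18 measured, 2 rose and 4 fell, or 5 and 8 when adjusted over the list alone. IL18, an inflammasome cytokine, fell by 1.08 on the log2 scale (SE 0.24, adjusted p = 0.00596), and the log2 changes of the monocyte chemokine CCL2, IL15 and the endotoxin receptor TLR4 were -1.4 ± 0.41, -0.78 ± 0.21 and -0.8 ± 0.25 (adjusted p = 0.0305, 0.018 and 0.0392). CXCL8, a neutrophil chemoattractant, rose by 1.32 ± 0.28 (adjusted p = 0.0039), but another probe of CXCL8 gave -2.03. TNF rose by 0.97 ± 0.28 (adjusted p = 0.0277), with 3 of 5 probes of the same sign. CXCR2, the neutrophil receptor for CXCL8, rose by 1.55 ± 0.19 (adjusted p = 2.14e-05) as the 1 called gene of the 7 in the neutrophil list (1 adjusted over the list alone). The median level of that list, which was not called, ran the other way, from -1.5 to -0.19 on the 1-week arrays and 0.05 to 3.94 on the control arrays. Fits without 1 array left IL18, CXCL8 and CXCR2 called. They ended the calls of CCL2 (without 1-week replicates 1, 3 or 4 or control replicates 1 or 2, adjusted p up to 0.0996), IL15 (1-week replicate 4, control 1 or 2, up to 0.0701), TLR4 (1-week 1 or 4, control 1, 2 or 3, up to 0.123) and TNF (1-week 2 or 4, control 1 or 4, up to 0.0984).

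Single members of further lists were called at 1 week. LUM, the collagen-binding proteoglycan lumican, was the 1 of 13 fibrous matrix genes to fall, by -1.33 ± 0.32 (adjusted p = 0.0105; 1 lower when adjusted over the list alone). In the protease list the urokinase gene PLAU changed by -1.06 ± 0.23 (adjusted p = 0.00557) and cathepsin L, CTSL, by -0.35 ± 0.11 (0.0493, with another probe at 0.02), with 14 genes not called and 1 lower when adjusted over the list alone. The osteoclast enzyme gene ACP5 (0.78 ± 0.24, adjusted p = 0.0414), the adipokine gene LEP (1.32 ± 0.36, 0.0195) and the immediate early gene EGR1 (at least 2.17-fold, 0.0148) were higher, each the 1 called gene of its list (1 adjusted over the list alone). CTSL was lost without 1-week replicates 3 or 4 or control 1, 2 or 3 (adjusted p up to 0.143), ACP5 without 1-week 2 or 4 or any control array (up to 0.122), LEP without 1-week 4 or control 1 or 3 (up to 0.0612) and EGR1 without 1-week 4 (0.0514), while LUM and PLAU held. Of the list genes named at 1 week, all separated the 4 and 4 arrays completely except CXCL8, TNF and PLAU, whose ranges overlapped.

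In all, 3745 probes were called at 1 week against control, 2612 higher and 1133 lower, and 88 named genes were higher and 63 lower. Of 765 named genes, 162 separated the groups completely, where chance gives 2.86%. With each array centred on its median instead, which shifts the median of all probes to -0.12, the split was 1851 higher and 1891 lower. The count was 2411 without control replicate 1 and 44 with normexp background correction. It was also lower in a fit to only the groups compared, which has fewer arrays, as given under the dependence on processing. Control and 1-week arrays were scanned on different days and share no batch, so scan day and time after surgery cannot be told apart in this comparison.

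The skeletal muscle list as a whole was lower than control at all 4 times. Its 16 measured genes had median log2 changes of -3.42, -3.66, -4.21 and -4.58 at 1, 2, 4 and 8 weeks, with 11, 7, 11 and 13 genes called lower and 13 at each time when adjusted over the list alone. With members below background set at their bound, the medians were -3.14, -3.56, -3.41 and -3.76. The camera test gave adjusted p = 3.15e-07, 1.57e-17, 7.67e-10 and 8.03e-11, and adjusted p = 0.882, 0.397, 0.68 and 0.68 with an estimated correlation, so none of the calls held with it; with fry the adjusted p were 0.0119, 0.00911, 0.00516 and 0.00516. The median muscle level of the control arrays was 1.66, 3.62, -1.51 and -1.77 in replicates 1 to 4, and the highest value on any operated array was -2.3. Without control replicates 1 and 2 the list medians were -1.18, -1.39, -1.83 and -2.29 at the 4 times, and 4, 5, 7 and 8 of the called genes kept their calls. Averaged over arrays, the difference was -3.45, -3.88, -4.29 and -4.5 at the 4 times (two-sided exact permutation p = 0.0286 each, the smallest that 4 against 4 arrays allow, n = 4). All 16 operated arrays against control differed by -4.03 (exact permutation p = 0.000206, the smallest possible). These permutations treat arrays as exchangeable, although each group lay on its own slide and the 1-, 4- and 8-week arrays on another scan day than control. They show that the arrays separate, not why. The 2-week and control arrays shared 1 scan day, so the median of -3.66 is itself a value within a day. A camera test with the 8 arrays of that day alone gave adjusted p = 8.26e-11 over the 11 lists, and adjusted p = 0.343 with an estimated correlation.

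**Figure D2:**
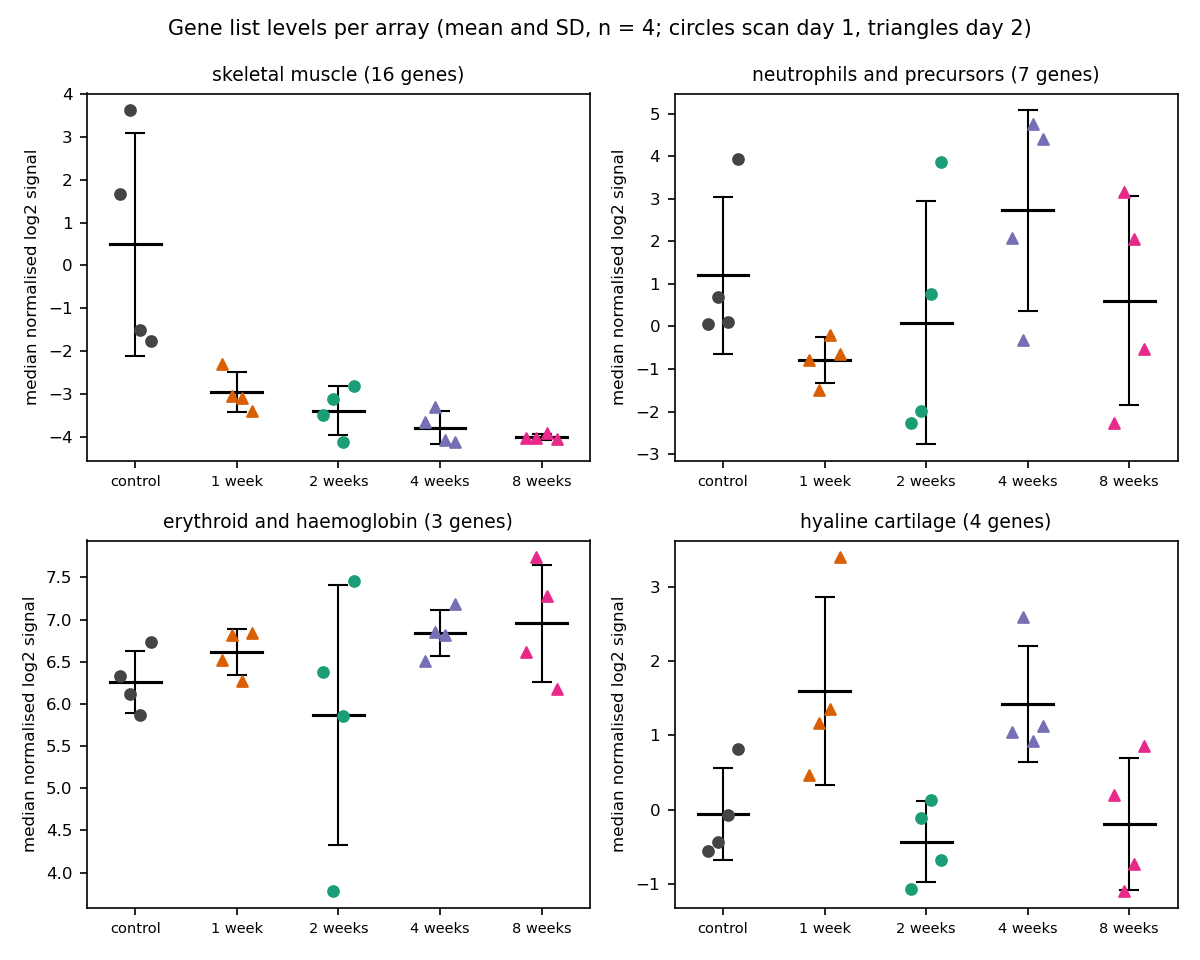
Median log2 level of the skeletal muscle, neutrophil, erythroid and hyaline cartilage lists on each array (y axis, log2 units; x axis, group), with group mean and SD, circles for the first scan day and triangles for the second. The muscle level is 1.66, 3.62, -1.51 and -1.77 on the control arrays and -2.3 or less on the 16 operated arrays.

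At 2 weeks after surgery, the called genes were mostly of muscle. MYH2 and TNNC2 changed by -6.61 ± 1.16 and -6.29 ± 1.06 (SE, adjusted p = 0.016 and 0.0129) and TTN by -5.61 ± 0.98 (0.0154). MYH8, MYH1, MYH7, the slow fibre myosin, and ATP2A1 were not well above background at 2 weeks and were at least 24-fold, 25.2-fold, 38.8-fold and 24.3-fold lower (adjusted p = 0.0379, 0.0129, 0.00156 and 0.0177). ANKRD1, a stretch-responsive muscle protein, was at least 4.93-fold lower (0.0318). At 2 weeks MYH2 was well above background on 1 of 4 arrays and TTN on 2, so their changes are fitted values, not measured sizes. With control replicates 1 and 2 left out, MYH8, MYH2 and ATP2A1 lost their calls, and the bounds of MYH1, MYH7 and ATP2A1 were 3.58-fold, 15.2-fold and 4.31-fold. Without control replicate 2 alone these bounds were 12.9-fold, 24.5-fold and 11.1-fold. Of 13 named genes called, 4 were higher: OVGP1 by 1.21 ± 0.25 (adjusted p = 0.0346), the connexin gene GJA5 by 0.91 ± 0.17 (0.0279), TH (0.0177), below background in both groups, and RSSD-1 (0.000216), above background on 3 of 4 of the 2-week arrays and with a bound under 1, so that no fold is given for either. All of them lay beyond the 4 control arrays in 4 of 4 arrays.

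Of these 2-week calls, MYH7 and RSSD-1 held without any 1 array. MYH1 was lost without control replicate 1 (adjusted p = 0.0514) and TNNC2 without that array or 2-week replicate 2 (up to 0.0575). MYH2 and TTN were lost without control replicate 1 or 2-week replicates 2 or 3 (up to 0.0728 and 0.0681). ATP2A1 was lost without 2-week replicates 1, 2 or 3 or control 1, and TH without 2-week 2 or 3 or control 1 or 2 (up to 0.0817 each). MYH8 was lost without 2-week 1, 2 or 3 or control 1 or 2 (up to 0.153), ANKRD1 without any 2-week array or control 1 (up to 0.1), GJA5 without 2-week 2, 3 or 4 or control 1 or 3 (up to 0.116), and OVGP1 without any array but 2-week 1 (up to 0.135).

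The list of hypoxia and glycolysis genes was shifted down at 2 weeks, with a median of -0.36 and all 8 measured genes below control (adjusted p = 0.0451, and adjusted p = 0.882 with an estimated correlation). None of its genes was called by limma, singly or adjusted over the list alone. The groups shared a scan day, so this median is itself a value within a day. With that day's arrays alone camera gave adjusted p = 0.0079 over 11 lists rather than 44 tests, and adjusted p = 0.343 with an estimated correlation. The median was -0.12 without the 2 control arrays of highest muscle level (adjusted p = 0.696). The call was also lost without control replicates 1 or 2 or 2-week replicate 4 (adjusted p = 0.24, 0.132 and 0.322), and without 1-week replicate 1 (0.0523). The inflammatory list had a median of -0.32, with 0 of 18 genes called (adjusted p = 0.0638, 0.882 with an estimated correlation; with that day's arrays over 11 lists 0.019, and 0.343 with an estimated correlation).

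In total 122 probes were called at 2 weeks, 65 higher and 57 lower, with 2086 at an unadjusted p under 0.05. The 4 higher and 9 lower named genes compare with 62 of 765 that separated the groups completely, where chance gives 2.86%. A limma fit to the 8 arrays of this scan day alone called 0 probes (2249 at an unadjusted p under 0.05). The count was 32, 33, 48 and 79 without control replicate 1, 2-week replicate 2, 2-week replicate 3 and control replicate 2, and 203 without control replicate 4.

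At 4 weeks after surgery, TNNC2 changed by -7.11 ± 1.06 (SE, adjusted p = 0.000322), MYH1 by -6.37 ± 1.05 (0.000843) and TTN by -5.43 ± 0.98 (0.00179). MYH8, MYH2, ATP2A1, MYH7 and CASQ2 were below background and at least 27.6-fold, 82.6-fold, 27.9-fold, 44.6-fold and 9.2-fold lower (adjusted p = 0.00251, 0.000877, 0.000571, 5.6e-05 and 0.00654). MYH1 was well above background on 1 of 4 arrays and TTN on 2, so their changes are fitted values, not measured sizes. The bounds of MYH2, ATP2A1 and MYH7 were 13.4-fold, 4.95-fold and 17.5-fold without control replicates 1 and 2. On the higher side, TH was at least 1.41-fold, GJA10 1.74-fold, CASP14 1.41-fold and PPARA 2.08-fold above control, where each was below background (adjusted p = 8.59e-06, 1.23e-07, 0.000325 and 0.00318). OVGP1 rose by 2.28 ± 0.25 (1.34e-05), KCNA3, a potassium channel of T cells, was at least 1.4-fold higher (0.0174), RSSD-1 at least 1.38-fold (3.45e-07), and HTR3B, a serotonin receptor subunit, was called with no fold given (7.24e-05). TH and KCNA3 were above background on 3 of 4 of the 4-week arrays and HTR3B on 1. All of these lay beyond the 4 control arrays in 4 of 4 arrays, and KCNA3 was the 1 that lost its call when an array was left out (4-week replicates 2 or 4, control 1 or 2, adjusted p up to 0.0549).

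The matrix protease list was shifted down at 4 weeks, with a median of -0.29 and 15 of 16 genes below control (adjusted p = 0.0497, and adjusted p = 0.882 with an estimated correlation; fry 0.0386). It had 3 genes called lower, or 4 when adjusted over the list alone: MMP12, the macrophage elastase, by -3.72 ± 0.92 (adjusted p = 0.0173), MMP3, stromelysin 1, by -1.01 ± 0.26 (0.0218) and PLAU by -1.02 ± 0.23 (0.0113). The list's call was lost without control replicates 1, 2 or 3 (adjusted p = 0.0992, 0.0524 and 0.113), without 4-week replicates 2, 3 or 4 (0.0708, 0.0757 and 0.0655), and without 1-week replicate 1 or 8-week replicates 2 or 3 (0.0552, 0.0506 and 0.0503). MMP12 was lost without 4-week replicates 2 or 3 or control 1 or 3 (up to 0.0657) and MMP3 without 4-week 2, 3 or 4 or control 2 or 3 (up to 0.0736), while PLAU held. MMP12 was well above background on 1 of 4 of the 4-week arrays.

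Of 4 macrophage genes measured, 2 fell at 4 weeks, CD14 by 1.29 on the log2 scale (SE 0.31, adjusted p = 0.0133) and the scavenger receptor MSR1 by 2.05 (SE 0.58, 0.0354), the 2 also called when adjusted over the list alone. Among 18 inflammatory genes, TNF and CXCL8 rose by 1.3 ± 0.28 and 1.18 ± 0.28 (adjusted p = 0.00651 and 0.0135), while IL1RN, the interleukin 1 receptor antagonist, IL15 and TLR4 changed by -1.14 ± 0.31, -0.75 ± 0.21 and -0.82 ± 0.25 (0.029, 0.0309 and 0.0478). Adjusted over the list alone, 3 were higher and 7 lower. Of the other probes of TNF, 2 gave -1.23 and -1.07, and the mean over all its kept probes was -0.05; 1 other probe of CXCL8 gave -2.02, so the direction of both depends on the probe. CXCR2 rose by 1.34 ± 0.19 (0.000191), LEP by 1.65 ± 0.36 (0.00721) and FRZB by 1.32 ± 0.34 (0.0229), each the 1 called gene of its list (1 adjusted over the list alone). LUM changed by -1.14 ± 0.32 (0.0354), the smooth muscle gene TAGLN by -1.65 ± 0.45 (0.0314) and the death receptor FAS by -0.78 ± 0.24 (0.05 after rounding), each again alone in its list (1, 2 and 1 adjusted over the list alone). When arrays were left out in turn, TNF, CXCR2 and LEP kept their calls, CD14 and CXCL8 lost them without 4-week replicate 4 or control 1 (adjusted p up to 0.0522 and 0.0517), and IL15 without 4-week 3 or 4 or control 1 or 2 (up to 0.111). IL1RN was lost without 4-week 1, 2 or 4 or control 2 or 3 (up to 0.0916), LUM, TAGLN, FRZB and MSR1 without 4-week 2, 3 or 4 or control 1, 2 or 3 (up to 0.125, 0.119, 0.0857 and 0.12), and TLR4 and FAS without any array but 4-week 1 (up to 0.144 and 0.158). Of the list genes called at 4 weeks, MMP12, MSR1, TNF, LUM and TAGLN overlapped the control range and the others lay beyond it in 4 of 4 arrays; MSR1 was well above background on 2 of 4.

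Altogether 2304 probes were called at 4 weeks, 1716 higher and 588 lower, with 73 named genes higher and 47 lower; 182 of 765 named genes separated the groups completely, where chance gives 2.86%. With median centring, which shifts the median of all probes to -0.1, the split was 1324 higher and 1165 lower. Leaving out 1 array gave 1302 (4-week replicate 2), 1319 (control 1), 1340 (4-week 4), 1472 (control 2) and 1504 (4-week 3), and up to 2711. Scan day and group cannot be told apart in this comparison.

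At 8 weeks the muscle genes remained the largest falls. TNNC2, MYH8 and MYL1, a myosin light chain, changed by -6.99 ± 1.06, -6.62 ± 1.33 and -6.41 ± 1.21 (SE, adjusted p = 0.000321, 0.00342 and 0.00215). MYH1, MYH2, MYH7, CASQ2 and the embryonic myosin MYH3 were below background and at least 34.4-fold, 98-fold, 52.9-fold, 10.9-fold and 8.89-fold lower (adjusted p = 0.000219, 0.000871, 7.12e-05, 0.00377 and 0.00521). These sizes rest on few control arrays. Without control replicate 2 the bounds of MYH1, MYH2 and MYH7 were 17.7-fold, 37-fold and 33.4-fold, and without replicates 1 and 2 they were 4.89-fold, 15.9-fold and 20.8-fold. With 1 array left out, the fitted log2 change of CASQ2 ran from -7.09 to -4.08 and that of MYH3 from -6.54 to -3.62; these are fitted values of genes below background, not measured sizes. MYL1 was well above background on 2 of 4 arrays and MYH8 on 1, so their changes too are fitted values, not measured sizes. Higher than control, where they were below background, were TH (at least 1.4-fold, adjusted p = 7.33e-06), GJA10 (1.67-fold, 8.62e-08), CASP14 (1.29-fold, 0.000434), PPARA (1.76-fold, 0.00564), UPK1B (2-fold, 0.00272) and SERPINB2, an inhibitor of plasminogen activators (2.08-fold, 0.00105). OVGP1 rose by 2.23 ± 0.25 (1.55e-05), and HTR3B was called with no fold given (4.14e-05). Each lay beyond the control arrays in 4 of 4 arrays and kept its call without any 1 array.

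Of the lists at 8 weeks other than muscle, none was called. PTGS1, the constitutive prostaglandin synthase, rose by 1.1 ± 0.22 (adjusted p = 0.00318) and CXCL8 by 1.17 ± 0.28 (0.0109, with another probe at -2.1), while IL1RN changed by -1.07 ± 0.31 (0.0293), and 3 inflammatory genes were higher and 1 lower when adjusted over the list alone. CXCR2 rose by 1.13 ± 0.19 (0.000676), LEP by 1.31 ± 0.36 (0.022) and ACP5 by 0.93 ± 0.24 (0.0179), and LUM and MMP12 changed by -1.19 ± 0.32 and -3.13 ± 0.92 (0.0219 and 0.0324). Each of these was the 1 called gene of its list, as when adjusted over the list alone except for MMP12 (0). PTGS1, CXCL8 and CXCR2 kept their calls without any 1 array. ACP5 was lost without 8-week replicate 3 or control 2 (adjusted p up to 0.066), LUM without 8-week 1 or control 1 or 2 (up to 0.0842), LEP without 8-week 1 or 3 or control 1 or 3 (up to 0.0659), IL1RN without 8-week 1, 3 or 4 or control 2 or 3 (up to 0.0881) and MMP12 without 8-week 1, 2 or 3 or control 1, 2 or 3 (up to 0.104). MMP12, above background on 1 of 4 arrays, overlapped the control range and the others lay beyond it in 4 of 4 arrays.

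The 8-week comparison called 3433 probes, 2275 higher and 1158 lower, and 71 named genes higher and 52 lower; 195 of 765 named genes separated the groups completely (2.86% by chance). With median centring, which shifts the median of all probes to -0.12, it was 1412 higher and 2207 lower. Without control replicate 2, 8-week replicate 1 or control replicate 1 the count was 2005, 2102 and 2134. Scan day and group cannot be told apart here either.

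**Figure D3:**
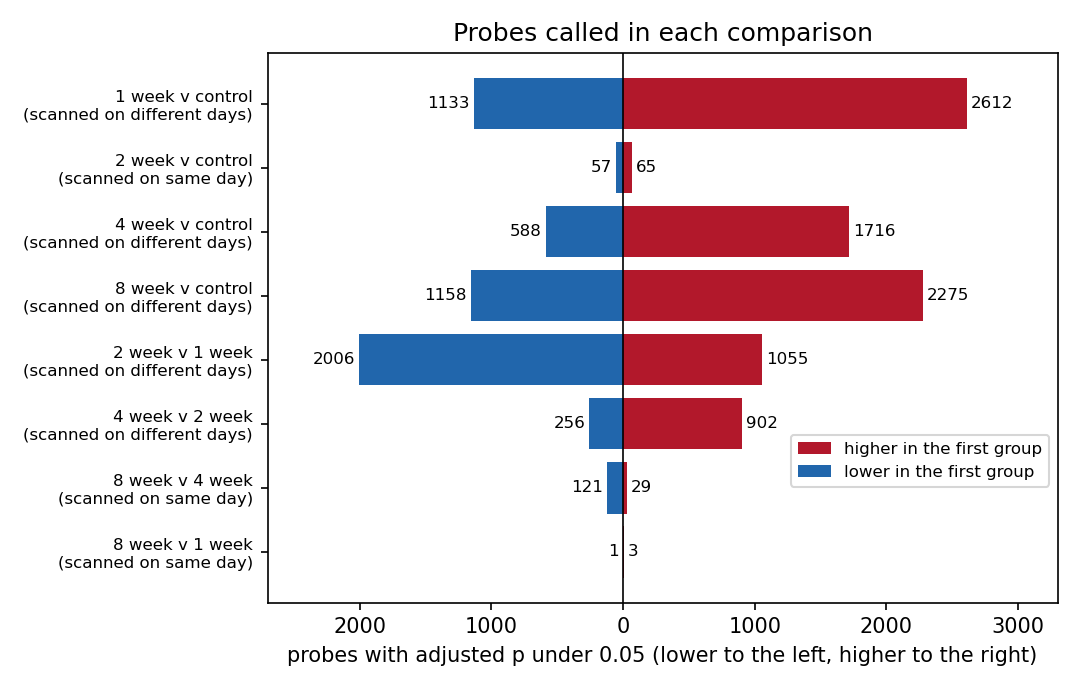
Number of probes called in the 8 planned comparisons (x axis, number of probes, lower to the left and higher to the right; y axis, comparison and whether the groups shared a scan day). The comparisons across scan days call between 1158 and 3745 probes, and those within a scan day 122, 150 and 4.

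Cartilage genes of the fixed panel differed from control by amounts that did not pass the test, apart from SOX9 at 1 week and MMP3 at 4 weeks. COL2A1, the main cartilage collagen (8.98 ± 0.5 in control, SD, n = 4), differed by 0.96, -0.44, 0.68 and -0.44 at 1, 2, 4 and 8 weeks (SE 0.51, adjusted p = 0.22, 0.931, 0.448 and 0.625). The proteoglycan gene ACAN differed by 1.02, -0.38, 0.58 and -0.02 (SE 0.39, adjusted p = 0.0865, 0.917, 0.385 and 0.983), and the hypertrophic collagen gene COL10A1 by 2.26, -0.09, 1.79 and -0.42 (SE 0.87, adjusted p = 0.0937, 0.996, 0.224 and 0.804). For the collagenase MMP13 the values were -0.63, -0.3, -0.58 and 0.01 (SE 0.26, adjusted p = 0.118, 0.895, 0.188 and 0.983), and for the aggrecanase ADAMTS5 -0.28, -0.09, -0.3 and 0.17 (SE 0.26, 0.495, 0.99, 0.513 and 0.722). TIMP1 differed by 0.24, 0.31, 0.06 and 0.39 (SE 0.25, adjusted p = 0.543, 0.867, 0.915 and 0.332) and IL1B by -1.62, -1.5, -0.57 and -1.62 (SE 0.67, adjusted p = 0.115, 0.606, 0.651 and 0.124). Single arrays moved these values: with 1 array left out, the 1-week differences ran from 0.53 to 1.28 for COL2A1, 0.57 to 1.25 for ACAN, -0.77 to -0.29 for MMP13, -0.42 to -0.09 for ADAMTS5 and 0 to 0.54 for TIMP1. At 4 weeks IL1B ran from -0.96 to -0.04, and at 8 weeks COL10A1 from -1.18 to 0.22 and COL2A1 from -0.82 to 0. ACAN at 1 week was called without 1-week replicate 1 (1.25, adjusted p = 0.0444), and MMP13 at 4 weeks with array weights (-0.65). COL1A1, PRG4 and VEGFA were not analysed here.

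**Figure D4:**
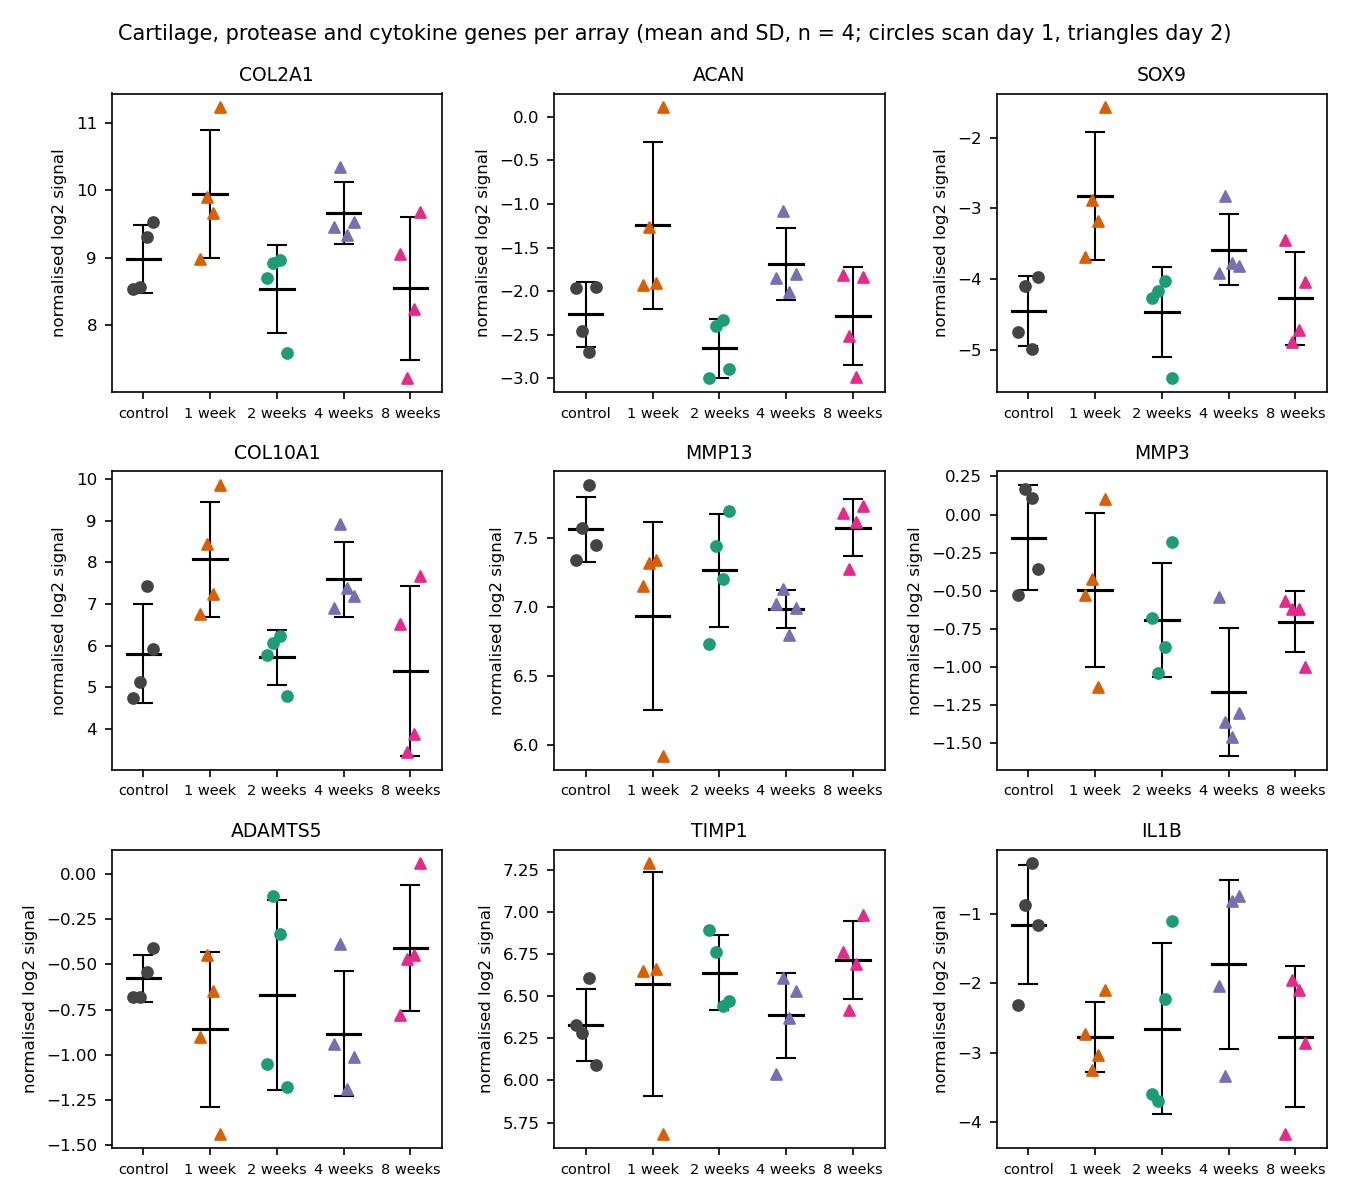
Log2 level of the panel genes on each array (y axis, log2 units relative to the array's 75th percentile; x axis, group), 1 point per array with the group mean and SD. COL2A1 has a control mean of 8.98 ± 0.5 and its 4 differences from control, -0.44 to 0.96, did not pass the test.

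The remaining lists tested against control were not called, and adjusted p at 1, 2, 4 and 8 weeks ran as follows. Hypertrophy gave 0.341, 0.968, 0.612 and 0.846, and fibrous matrix 0.905, 0.905, 0.696 and 0.612. Protease inhibitors gave 0.881, 0.4, 0.891 and 0.74, osteoclasts 0.696, 0.968, 0.673 and 0.612, and neutrophils 0.863, 0.28, 0.341 and 0.968. TGF-beta and BMP signalling gave 0.797, 0.398, 0.891 and 0.797, and WNT and hedgehog signalling 0.673, 0.612, 0.612 and 0.751. Some medians, means and tests differed in sign: fibrous matrix at 1 and 2 weeks (medians 0.05 and 0.08, means -0.02 and -0.04, test down), inhibitors at 1 week (0.2, mean -0.02, down), osteoclasts at 1 week (-0.29, mean 0.02, down) and 2 weeks (-0.02, mean -0.07, up), neutrophils at 8 weeks (-1.24, mean -0.68, up) and hypoxia at 4 weeks (-0.01, mean 0.02, down). Lists with fewer than 5 measured genes were not tested as lists. None of their genes was called against control among MX2 (interferon), DLX5 (osteoblast), CD5 (lymphocyte), NEFM (nerve), the erythroid genes HBA, HBB2 and CA1, the endothelial genes KDR and SELE, the cell cycle genes CCNA2 and CCNE1, the chaperone genes CALR, SERPINH1 and HSP90B1, or the synovial genes CLU, HAS2, FN1 and VCAM1; no oxidative phosphorylation gene was measured.

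Comparisons with control share the 4 control arrays. Those at 1, 4 and 8 weeks also set groups of 1 scan day against controls of the other. A difference between days would enter these comparisons alike, also with split controls, so their overlap cannot be told apart from it. The 1- and 4-week comparisons called 1287 probes higher and 299 lower together, the 1- and 8-week comparisons 1622 and 504, and the 4- and 8-week comparisons 1240 and 298. Independent lists of the same sizes would share 167 and 24.8, 221 and 48.8, and 145 and 25.3. Unchanged groups against the same controls shared 0 in the mean of 100 simulations. Those simulations held no group differences, so few or no probes were called that could be shared, and their counts are no baseline for the overlap. With the control arrays split between the comparisons, 589 to 832, 769 to 1027 and 573 to 656 probes were shared in the same direction. The log2 changes correlated across probes with r = 0.776, 0.769 and 0.768 (0.497, 0.501 and 0.518 simulated), with covariances of 0.334, 0.323 and 0.301 (0.0616, 0.06 and 0.0634 simulated). With split controls r was lower, at 0.396 to 0.658, 0.413 to 0.623 and 0.399 to 0.663. The covariances were then 0.214 to 0.302, 0.216 to 0.285 and 0.191 to 0.276. The 2-week comparison shared 56 higher and 41 lower probes with that at 1 week, 60 and 47 with that at 4 and 58 and 45 with that at 8 weeks (independent lists 6.31 and 2.4, 4.15 and 1.25, and 5.5 and 2.45; simulated 0, 0.01 and 0; split controls 8 to 81, 8 to 93 and 8 to 95), with r = 0.491, 0.597 and 0.642 (0.479, 0.503 and 0.488 simulated; with split controls 0.0909 to 0.338, 0.0892 to 0.478 and 0.148 to 0.431) and covariances of 0.155, 0.176 and 0.184 (0.058, 0.0623 and 0.0591 simulated).

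Between 1 and 2 weeks, 3 of the 4 measured hyaline cartilage genes fell, and COL2A1 was not called. CNMD, the cartilage angiogenesis inhibitor chondromodulin, changed by -2.65 ± 0.83 (SE, adjusted p = 0.0483) and ACAN by -1.41 ± 0.39 (0.0253), and SOX9, not well above background at 2 weeks, was at least 1.93-fold lower (0.0214). All 4 measured genes of the hyaline list were lower when adjusted over the list alone. RUNX2, the transcription factor of hypertrophy and bone, changed by -0.65 ± 0.18 (0.0246), the 1 called of 6 hypertrophy genes (4 adjusted over the list alone). In the WNT list FRZB and WNT11 changed by -1.67 ± 0.34 and -1.87 ± 0.48 (0.00346 and 0.0186) and WNT3 by 1.98 ± 0.41 (0.004), with 2 higher and 3 lower adjusted over the list alone. CXCR2, CXCL8 and LEP changed by -1.56 ± 0.19, -1.41 ± 0.28 and -1.62 ± 0.36 (2.64e-05, 0.00285 and 0.00626), with another CXCL8 probe at 0.59. HAS2, which makes hyaluronan, EGR1 and the glucose transporter SLC2A1 were lower (-1.5 ± 0.43, -1.54 ± 0.35 and -1.37 ± 0.43; 0.0327, 0.00811 and 0.0486), IL18 was higher (0.84 ± 0.24, 0.0315), and CD5, below background at 2 weeks, was at least 1.7-fold lower (0.0129).

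Other changes between 1 and 2 weeks included GJA10, SERPINB2 and the adrenergic receptor gene ADRA1D, which fell below background and were at least 2.4-fold, 2.5-fold and 1.66-fold lower (adjusted p = 7.26e-09, 7.2e-05 and 8.39e-05). F2, prothrombin, WNT3, the pacemaker channel HCN4 and GSTM2, a glutathione transferase, rose by 2.1 ± 0.58, 1.98 ± 0.41, 1.64 ± 0.33 and 1.49 ± 0.43 (0.0268, 0.004, 0.00334 and 0.0344). Without 1-week replicate 4 or 2-week replicate 4 the calls of SOX9, WNT11, RUNX2, ACAN, HAS2, IL18, SLC2A1 and CNMD were lost. Further losses came without 2-week 1 (RUNX2), 1-week 2 or 2-week 1 (ACAN), 1-week 2 or 2-week 3 (HAS2), 1-week 1 or 2-week 3 (IL18), 1-week 2 or 2-week 2 or 3 (SLC2A1), 1-week 2 or 4 or 2-week 1, 2 or 3 (GSTM2), 1-week 1 or 2 or 2-week 1 or 2 (F2), and any array but 1-week 1 (CNMD), with adjusted p up to 0.158. Of the genes named, EGR1 and SLC2A1 overlapped between the groups and the others separated 4 from 4 arrays. The count was 3061 probes, 1055 higher and 2006 lower (41 and 78 named genes; 143 of 765 separated completely, 2.86% by chance). Median centring, which shifts the median of all probes to 0.17, gave 2309 higher and 1566 lower, and only the groups compared gave 1180. The groups were scanned on different days, so day and time cannot be told apart.

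From 2 to 4 weeks, the list of neutrophil genes shifted up, with a median of 2.52 and 7 of 7 genes above 0 (adjusted p = 0.0478, and adjusted p = 0.841 with an estimated correlation; fry 0.0972). CXCR2 alone was called (1.35 ± 0.19, SE, adjusted p = 0.00027), with 2 higher when adjusted over the list alone. The 3 erythroid genes, too few for a list test, had a median of 0.97, with 3 of 3 above 0 and 0 called. The neutrophil level of single arrays ran from -2.27 to 3.86 at 2 weeks and from -0.32 to 4.76 at 4 weeks, and the list's call was lost without 4-week replicates 3 or 4 (medians 1.67 and 1.95, adjusted p = 0.0852 and 0.0884) or 2-week replicate 2 (1.68, 0.0677), and without any of control replicates 1, 2 and 3 (0.0573, 0.0536 and 0.0614) or 1-week replicates 1 and 4 (0.0639 and 0.0534), which are not part of the comparison. FRZB and LEP rose by 1.7 ± 0.34 and 1.94 ± 0.36 (0.00647 and 0.00323), CXCL8 by 1.26 ± 0.28 (0.0132, with another probe at -0.57) and TNF by 1.07 ± 0.28 (0.0357, with others at -0.72 and -0.75). GJA10, SERPINB2 and CASP14, below background at 2 weeks, were at least 1.7-fold, 1.75-fold and 1.38-fold higher (1.33e-07, 0.00114 and 0.00378), and APOC4 rose by 2 ± 0.33 (0.00118). The falls were small: SLC7A8, an amino acid transporter, by -0.57 ± 0.15 (0.0422), the chaperone CALR by -0.52 ± 0.12 (0.0166), the dehydrogenase DHRS4 by -0.51 ± 0.11 (0.0139) and cytoplasmic actin, ACTG1, by -0.5 ± 0.1 (0.00605).

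Each of the genes named for 4 against 2 weeks separated 4 from 4 arrays. CXCL8 was lost without 2-week replicate 1 or 4-week replicate 4 (adjusted p up to 0.0555), DHRS4 without 2-week 2 or 4-week 2 (up to 0.0631), CALR without 2-week 4 or 4-week 2 or 3 (up to 0.0629), TNF without any array but 2-week 4 and 4-week 4 (up to 0.125) and SLC7A8 without any but 4-week 1 (up to 0.141). The comparison called 1158 probes, 902 higher and 256 lower (37 and 9 named genes; 141 of 765 separated completely, 2.86% by chance). With median centring, which shifts the median of all probes to -0.16, it called 793 higher and 988 lower. Without 4-week replicates 4 or 2 the count was 677 and 679. Scan day and time cannot be told apart here.

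The later comparisons lay within 1 scan day and called 150 probes from 4 to 8 weeks and 4 from 1 to 8, but 1926 and 405 with array weights. From 4 to 8 weeks KCNQ1, a potassium channel, and CRYAA, an alpha crystallin, changed by -1.35 ± 0.22 and -1 ± 0.19 (SE, adjusted p = 0.00589 and 0.0144), each lower in 4 of 4 arrays. Of 765 named genes 3 were called, and 96 separated completely (2.86% by chance). The call of CRYAA was lost without 4-week replicates 2 or 3 or 8-week replicate 2 (up to 0.0665). In all 150 probes were called, 29 higher and 121 lower, with 62 in a fit to that day's arrays alone. Without 4-week replicate 3 or 8-week replicate 2 the count was 93, without 8-week replicate 3 it was 95 and without 4-week replicate 2 it was 97.

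No list was called between 4 and 8 weeks in the planned test. The protease list had a median of 0.36 with 15 of 16 genes above 0, and the osteoclast list 0.33 with 8 of 8 (adjusted p = 0.0605 each, 0.841 with an estimated correlation), WNT and hedgehog genes -0.62 (0.0654, 0.592 with an estimated correlation) and neutrophil genes -1.8 (0.0897, 0.841). With that scan day's arrays alone, adjusted over 11 lists rather than 44 tests, each of these 4 had adjusted p = 0.0223, and adjusted p = 0.611, 0.611, 0.237 and 0.611 with an estimated correlation, so calls at the preset correlation were lost with the estimated one. From 1 to 8 weeks the osteoclast list had a median of 0.38 (0.0655) and hypoxia genes -0.49 (0.0605), each with adjusted p = 0.841 with an estimated correlation, and the muscle list -0.53 (0.163, and 0.923). With that day's arrays over 11 lists, adjusted p was 0.0306, 0.0306 and 0.00273, and adjusted p = 0.441, 0.441 and 0.397 with an estimated correlation.

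Between 1 and 8 weeks limma called 4 probes, 3 higher and 1 lower, with 3939 at an unadjusted p under 0.05, and none of the 765 named genes, of which 82 separated completely (2.86% by chance). The 4 probes are unnamed here: A_04_P024034 and A_04_P101302 rose by 2.51 ± 0.32 and 1.67 ± 0.23 (SE, adjusted p = 0.0118 and 0.0193) A_04_P014182 by 1.2 ± 0.19 (0.0391), and A_04_P068306 changed by -2.63 ± 0.38 (0.0236). The fit to that scan day alone called 1 probe, and the count was 79 without 1-week replicate 4. The added comparison of 4 weeks with 1 week called 289 probes, 243 higher and 46 lower, 192 with that day's arrays alone. A fit to only the groups compared, which has fewer arrays, called far fewer probes, as given under the dependence on processing. For 4 weeks against 1 week the neutrophil list had a median of 2.93 and the muscle list -0.81 (camera adjusted p = 0.0136 and 0.00952 over 11 lists with that day's arrays, and adjusted p = 0.854 and 0.574 with an estimated correlation). With all arrays in the fit the preset correlation gave 0.0478 and 0.653 over the 11 lists, so the muscle call was lost there.

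Other lists were not called between times. Adjusted p for 2 against 1, 4 against 2, 8 against 4 and 8 against 1 week were 0.239, 0.535, 0.639 and 0.237 for hypertrophy, 0.88, 0.639, 0.864 and 0.639 for fibrous matrix, 0.402, 0.639, 0.75 and 0.297 for protease inhibitors and 0.864, 0.987, 0.75 and 0.587 for inflammatory mediators. They were 0.815, 0.639, 0.815 and 0.963 for TGF-beta and BMP signalling, and 0.864, 0.577, 0.75 and 0.163 for skeletal muscle. The first 2 comparisons gave 0.864 and 0.815 for WNT and hedgehog genes, 0.17 and 0.239 for hypoxia, 0.395 and 0.145 for proteases and 0.619 and 0.575 for osteoclasts; hypoxia had 0.144 for 8 against 4, and for 8 against 1 WNT genes had 0.171, proteases 0.163 and neutrophils 0.762. Neutrophil genes had 0.69 for 2 against 1. Medians, means and tests differed in sign for fibrous matrix (2 against 1, -0.06, -0.01, up; 4 against 2, 0.02, -0.14, down), osteoclasts and neutrophils (2 against 1, 0.29, -0.09, up, and 0.41, 0.17, down), inflammatory mediators (2 against 1, -0.02, 0.06, up; 4 against 2, -0.16, 0.02, up), WNT genes (4 against 2, -0.04, 0.2, up), muscle (8 against 4, 0.06, -0.1, down) and TGF-beta genes (8 against 1, 0.06, -0.04, up).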

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

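In this part, the tests of a lasting change, of quantile normalization, of scan day, of muscle tissue in the controls, and of erythroid and cartilage levels beside the neutrophil list were chosen only after the result was seen. The tests of GC content, of the control array richest in muscle and of array brightness had been written down beforehand.

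Of 175 groups of 4 arrays examined, 11 had an array far from the other 3 by a gap test that chance passes in about 1 of 20 groups, or 8.75 expected. Replicate 4 of the 1-week group stood apart in its correlation with its own group (gap 0.886 of the range) and in GJA10 (0.965) and MMP13 (0.866). Other gaps were those of MMP3 (0.884) and MYH8 (0.952) in 8-week replicate 4, MYH1 in 4-week replicate 3 (0.945), and SOX9 in 4-week replicate 2 (0.87). Among the lists they were neutrophils in control replicate 4 (0.833), skeletal muscle in 8-week replicate 3 (0.857), and hypoxia in 4-week replicate 2 (0.851) and control replicate 1 (0.882).

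Tested differences between times set the following genes apart. From 1 to 2 weeks the log2 differences were ACAN -1.41, ADRA1D -2.74, CD5 -1.71, CNMD -2.65, CXCL8 -1.41, CXCR2 -1.56, EGR1 -1.54, F2 2.1, FRZB -1.67, GJA10 -3.04, GSTM2 1.49, HAS2 -1.5, HCN4 1.64, IL18 0.84, LEP -1.62, RUNX2 -0.65, SERPINB2 -2.81, SLC2A1 -1.37, SOX9 -1.64, WNT11 -1.87 and WNT3 1.98. From 2 to 4 weeks they were ACTG1 -0.5, APOC4 2, CALR -0.52, CASP14 1.95, CXCL8 1.26, CXCR2 1.35, DHRS4 -0.51, FRZB 1.7, GJA10 2.55, LEP 1.94, SERPINB2 2.3, SLC7A8 -0.57 and TNF 1.07, with 2.52 for the median of the neutrophil list. From 4 to 8 weeks they were CRYAA -1 and KCNQ1 -1.35. The values of genes below background in 1 of the groups (ADRA1D, CASP14, CD5, GJA10, SERPINB2 and SOX9) are fitted values, not measured folds.

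The first pattern is that comparisons across scan days called 1158 to 3745 probes and those within a scan day 4 to 289, or 3556 to 5763 and 373 to 1926 with array weights; leaving out 1 array took 4 against 2 weeks down to 677 and, in another fit, 4 against 1 week up to 749. A lasting response of similar size would leave probes called the same way at 1, 4 and 8 weeks moved at 2 weeks as well. The median move of those 1335 probes was 0.24 at 2 weeks, the group scanned with control, beside 1.42, 1.17 and 1.18. At 2 weeks 78.3% kept their direction and 104 were called. Picking probes by their calls at 1, 4 and 8 weeks raises the medians at those times. Those comparisons cross scan days, so the choice also favours probes that move with the day. These probes thus moved less at 2 weeks, but that does not decide on a lasting response. With the trend on probe GC content removed, the smallest count across days was 1533 and the largest within a day 386, and with quantile normalization they were 784 and 373. This argues against GC content or differing signal distributions as the whole cause. Beside 1158 and 289 without these steps, a part played by either is not excluded. The pattern did depend on background correction, because with normexp 4 against 2 weeks called 3 probes and 8 against 4 called 15, or with bright backgrounds replaced 88 against 112 for 4 against 1 week, so background in dim probes stays open as a part of it. No group (0) had arrays on both scan days, so scan day, with the slides and labelling that went with it, cannot be told apart from time after surgery or a pause at 2 weeks, and arrays of each group from both days would settle it.

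The second pattern is the low muscle transcripts at all 4 times. Scan day does not account for it at 2 weeks, where the list median was -3.66 against control arrays of the same day. Nor does 1 control array alone, since without replicate 2 the medians were -2.19, -2.47, -3.01 and -3.28 and the highest adjusted p 3.65e-06 at the preset correlation, though no muscle call held with an estimated one; without replicates 1 and 2 the medians shrank to -1.18, -1.39, -1.83 and -2.29, so much of the size rests on those 2. All 16 measured genes were highest in that replicate, and control levels ran from -1.77 to 3.62, which fits muscle tissue taken along with the control cartilage in differing amounts. A loss of muscle near the joint after surgery, the biological alternative, was not tested apart from this. Whether such tissue in the controls also shifts genes outside the muscle list was not tested for each gene.

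The third pattern is the wide spread of neutrophil transcripts within groups, from -2.27 to 4.76 over the arrays. Within groups their level went with that of erythroid genes (r = 0.605 over 20 arrays, permutation p = 0.0364, adjusted p = 0.109 over 3 relations, Spearman 0.514 with p = 0.0601, 0.464 without the 2 arrays farthest out, 0.671 and 0.577 within the scan days), which fits blood or marrow in differing amounts, though not after adjustment. Its relation to array brightness (r = 0.099, permutation p = 0.598, interval -0.417 to 0.567) and to hyaline cartilage genes (r = -0.23, permutation p = 0.307, interval -0.651 to 0.3) could not be told from 0, with opposite signs in the first and second scan day (-0.573 and 0.429 for brightness, 0.406 and -0.547 for cartilage). No biological explanation of this spread was tested.

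Splits of the same arrays argue against chance for the probe counts, except at 2 weeks and for 8 against 1 week, where other settings called 0 probes. The smallest share that 35 splits allow is 1 of 35, not adjusted over the comparisons. Each group lay on its own slide, so the splits cannot tell a slide or scan day difference from one of time. The real count and the highest of any other of the 35 splits were 3745 and 5 at 1 week, 122 and 39 at 2, 2304 and 5 at 4, and 3433 and 3 at 8 weeks against control. They were 3061 and 348 for 2 against 1, 1158 and 30 for 4 against 2, 150 and 6 for 8 against 4, 4 and 1 for 8 against 1 and 289 and 1 for 4 against 1, the real split being the 1 as large in each case. For the F test they were 4260 and 141 (1 of 100 splits). Chance cannot be excluded for the number of lists called, 6 and 15 against control (39 of 100 splits as large) and 1 and 14 between times (95 of 100).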

How the results depend on the processing

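Several settings in this part were chosen only after the result was seen: normexp with bright local background replaced, the fit without the 2 control arrays richest in muscle, median centring for the lists, the list tests within a scan day, and the comparison of 4 weeks with 1 week. Unless a cause is given, the cause was not tested.

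Over 192 named gene changes and 4503 alternatives, 3727 stayed the same, 704 were weaker, 2 stronger, 52 moved and 18 reversed. Normexp left 34 of the 192 the same, with 149 weaker, 4 moved and 5 reversed, and with bright backgrounds replaced 84 were weaker and 2 moved. Without the 2 control arrays richest in muscle, 89 of 156 changes stayed the same, 64 were weaker and 3 moved. That fit also has fewer control arrays, and the 156 include muscle genes. Over 12 counts and 313 alternatives 188 stayed and 125 moved by over 1.5 times; over 7 called list shifts and 214 alternatives 175 stayed and 39 were weaker. Slide as a block was not run because each slide holds 1 group, and scan day as a block was not run for comparisons across days or the F test because no group has both days. For the comparisons within a day it could change no count, so those alternatives add nothing to the stayed ones.

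Normexp background correction gave 44, 0, 28 and 35 probes at 1, 2, 4 and 8 weeks against control (limma, with 543 at an unadjusted p under 0.05 at 2 weeks), 46, 3, 15 and 0 for 2 against 1, 4 against 2, 8 against 4 and 8 against 1 (1205 at an unadjusted p under 0.05 for the last), 73 in the F test, 13 for 4 against 1, and 11 and 12 lists called against control and between times. A few spots narrowed the spread of 2 arrays: 15 spots on 2-week replicate 4 lay as far as -43300 below their local background and 1 spot on control replicate 3 lay at -3270, and the interquartile range fell from 3.81 to 0.83 and from 3.77 to 1.98. With such backgrounds replaced the ranges were 2.79 and 2.8, and the counts 2094, 1, 519 and 1120 against control, 1476, 88, 86 and 0 between times (3607 at an unadjusted p under 0.05 for 8 against 1), 1875 (F), 112 (4 against 1) and 6 lists between times. Most counts thus stayed below those without normexp, and why was not tested.

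Requiring signal on all 20 arrays, which tests fewer probes, gave 2218, 8, 933 and 2139 against control, 1716, 394, 98 and 0 between times (2888 at an unadjusted p under 0.05 for 8 against 1), 2754 (F) and 142 (4 against 1), and no filter gave 74 at 2 weeks and 38 for 8 against 1. Array weights gave 373, 5112 and 5763 at 2, 4 and 8 weeks, 3556, 1926 and 405 for the last 3 comparisons between times, 8211 (F) and 953 (4 against 1). A 2-fold threshold gave 1677, 1171 and 1149 at 1, 4 and 8 weeks, 1416, 607 and 75 for the first 3 between times, and 154 for 4 against 1. Only the groups compared gave 1397 at 1 week, 0 at 2 weeks (2249 at an unadjusted p under 0.05), 1180 for 2 against 1, 251 for 8 against 4, 0 for 8 against 1 (2875) and 29 for 4 against 1, and the arrays of 1 scan day 0, 62, 1 and 192 for 2 weeks, 8 against 4, 8 against 1 and 4 against 1. Without the 2 control arrays richest in muscle the counts were 1480, 54, 771 and 965, 2466 (F) and 6 lists between times. Median centring moved 4 against 2 to 1781 and 8 against 1 to 9; for 8 against 1, quantile normalization gave 35, trend with robust variance 2 and the GC correction 11. The GC correction split the calls at 1, 4 and 8 weeks into 1936 and 1501, 1338 and 1107, and 1517 and 1396 higher and lower. Of the lists between times, quantile normalization called 3, the mean over probes 5 and fry 0 (5 at an unadjusted p under 0.05), and an estimated correlation 0 (1) and, against control, 0 (3).

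Replicate number as a block moved 8 against 1 to 7 probes; otherwise it gave 3568, 101, 2175 and 3288 against control, 2904, 1106 and 127 between times, 3760 (F) and 4 and 1 lists. The replicate numbers gave no sign of pairing: over 40 pairs of the same number the deviations correlated with a median of 0.008, and in 10 of 40 the best match had the same number, as about 1 in 4 would by chance. Slide position equals the replicate number except in the 8-week group. For position the median was 0.02 and the best match had the same position in 15 of 40. A weak effect of position is therefore not excluded.

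Called list shifts were lost as follows. With an estimated correlation adjusted p was 0.882, 0.397, 0.68 and 0.68 for muscle, 0.882 for hypoxia and for proteases and 0.841 for neutrophils; with fry 0.31 for hypoxia and 0.0972 for neutrophils. With bright backgrounds replaced after normexp, proteases had -0.23 (0.0643). With the replicate block hypoxia and proteases had 0.0549 each, with array position as a block 0.0625 and 0.0576, with median centring -0.34 (0.0596) and -0.42 (0.0765), and without the 2 control arrays richest in muscle -0.12 (0.696) and -0.31 (0.0876). Without those 2 arrays the muscle list stayed called but had -1.18, -1.39, -1.83 and -2.29.

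Leaving out 1 array gave ranges of 2411 to 4298 (1 week), 32 to 203 (2 weeks), 1302 to 2711 (4 weeks) and 2005 to 3901 (8 weeks) against control, 2042 to 3565, 677 to 1456, 93 to 172 and 0 to 79 between times, 3175 to 5371 (F), 191 to 749 (4 against 1), and 4 to 8 and 0 to 7 lists. For 8 against 1 the count was 0 without 8-week replicates 2 or 3 (3074 and 3028 at an unadjusted p under 0.05), 1 without 8-week 1, 2 without 8-week 4, and 9, 12, 15 and 79 without 1-week 2, 1, 3 and 4; for 4 against 1 it was 191 and 192 without 4-week 3 and 1-week 2 and 749 without 1-week 4.

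Reversed were, with normexp, CASP14 and GJA10 in 4 against 2 (-0.15 and -0.02), HTR3B at 4 and 8 weeks (-0.14 and -0.02) and KCNA3 at 4 weeks (-0.07). Other probes reversed CTSL at 1 week (0.02), CXCL8 at 1, 4 and 8 weeks (-2.03, -2.02 and -2.1; adjusted p = 0.0143, 0.0218 and 0.0131), in 2 against 1 (0.59) and 4 against 2 (-0.57), and TNF at 1 week (-0.69 and -0.52), 4 weeks (-1.23 and -1.07) and in 4 against 2 (-0.72 and -0.75). The mean over probes reversed TNF at 4 weeks (-0.05).

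Signal over background limits the dim genes: of the calls higher than control, 56.6%, 70.8%, 66.4% and 59.2% at 1, 2, 4 and 8 weeks lay in the dimmest of 3 equal classes of probes. Of the lower calls, the brightest class held 526, 1, 263 and 736 at these times and the dimmest 296, 50, 200 and 218.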

Other observations

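The immunoglobulin probes below were examined only after the result was seen.

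Probes described as rearranged immunoglobulin variable regions, which mark B cells and plasma cells, numbered 1245 on the array and 164 among those kept. Most thus failed the filter on signal, which keeps a probe that is bright in only 1 group. Over all 26905 kept probes, 2612 were called higher and 1133 lower at 1 week. At 4 weeks these counts were 1716 and 588, and at 8 weeks 2275 and 1158. Of the 164 immunoglobulin probes, at 1 week 49 were called higher than control and 2 lower (median log2 difference 0.34, quartiles -0.71 to 1.32), at 4 weeks 42 and 1 (median 0.46) and at 8 weeks 39 and 4 (median 0.22). At 2 weeks limma called 0 either way (median -0.11). From 1 to 2 weeks 2 were higher and 50 lower, from 2 to 4 weeks 28 higher and 0 lower, and 0 were called from 4 to 8 or from 1 to 8 weeks. These probes target related genes and were not treated as independent measurements, and the comparisons with calls are those across scan days.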
